A study of Mus musculus with 87 samples.

How the data were processed

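The series holds 87 libraries from C57BL/6 mice: 46 made by ATAC-seq, in which Tn5 transposase inserts sequencing adapters into accessible DNA, 34 by RNA-seq and 7 by chromatin immunoprecipitation or as its input. The values analysed here are 10 ATAC-seq peak lists, each of which stands for 2 libraries of a single sorted cell population, so that 20 libraries lie behind them. The other 67 libraries, 26 of them ATAC-seq, were not analysed here. Per the labels' protocols, each ATAC-seq reaction used 50000 cells and the libraries were sequenced as paired-end reads for 50 cycles.

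Each deposited list gives the start and end of every peak, a name and a score, and per its name each list holds the peaks shared by both replicates of its population. The score deposited by the authors is 1 for every peak in all 10 lists and was not used to rank or filter peaks. The number that ends each peak name ran from 2 to 7, and each name reads as a merged peak with its centre; these numbers were used only to take the centre and to count how many intervals had been joined. The submitters' processing notes name Bowtie 0.12.8, MACS 1.4.2, HOMER, bedtools, SICER, TopHat2 2.0 and CASAVA 1.8.2 and the mouse build mm9, without saying which tool made which file. The peak threshold, the treatment of duplicate reads and whether read ends were shifted for the transposase offset are not given in the sources used here. Coordinates are those of mm9, counted from 1.

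The gene table used for reference is of GRCm38, and on 10 of 20 chromosomes compared the last peak ends beyond the last gene of that table. No gene was therefore assigned to any region, and the planned comparisons of gene lists and of promoter with distal regions were not run. By the rule fixed for this case, the text names the 5 densest 100 kb windows of each mature population by position.

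Peaks of all 10 lists that overlapped by at least 1 bp were merged into 111690 regions covering 62.2 Mb, with a median width of 430.0 bp. A region counted as listed in a population when a peak of that population's list lay in it. Absence from a list means that no peak passed the authors' threshold in both replicates, which is not the same as closed chromatin. Similarity of a pair of lists was the Jaccard index, the base pairs covered by both lists divided by those covered by either. Each region of a mature list was given the earliest listed stage in the order HSC, MPP, CLP, then NKp and iNK for NK cells, ILC2p for ILC2, and no further stage for either ILC3 list. Shares of regions carry 95% exact (Clopper-Pearson) binomial intervals, and ratios of shares carry 95% intervals on the log scale. Neighbouring regions are not independent and the lists have no replicate values, so these intervals cover counting error only.

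Tests were made only across lists. The number of peaks, the covered length and the peak width of the 4 mature and 6 bone marrow lists were compared by two-sided exact permutation tests over all 210 splits of the 10 lists, and mean similarity within against between these classes by a one-sided exact permutation test over the same splits, with a threshold of 0.05. Each population gives a single list, so a p-value here measures the spread between populations, not between animals. The densest windows were set beside 1000 random draws of as many regions from the merged set, as a description. The number of reads behind each list is unknown, which leaves open how far the length of a list reflects depth.

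The description labels start with an identifier that is read here as a sequencing run, which is an interpretation, and these identifiers fall into sets, called A to D here. Both libraries of HSC, MPP and CLP came from set A and both of NKp and ILC2p from set B. The iNK libraries came from A and B, those of NK, NCR ILC3 and CD4 ILC3 from D and B, and those of ILC2 from D and C. Every mature list therefore has a library of set D, and no bone marrow list has.

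Apart from the comparisons of peak width, the tests, the comparisons and most alternatives were fixed before the data were examined. The alternatives were a region counted only where the list's peaks cover at least 50% of it, peaks set to 200 bp around their centre, lists thinned at random to the length of the shortest, autosomes only, peak pairs overlapping by 1 bp or by 50% reciprocally in place of merged regions, 50 kb windows, and others specific to a single result. The wider peaks of each list, leaving out each list in turn, and the NCR ILC3 or HSC list reduced to its widest peaks were added after seeing the data. The scripts were tested on simulated data: over 90 pairs of lists and 111690 regions the recovered shares differed from the planted ones by 0 percentage points. Simulated peaks of the same region always overlapped, so this checks the counting and not the choice of overlap rule. The exact permutation test of similarity gave p = 0.00476 for planted classes, and 6.5% of 200 draws without classes fell below 0.05. Merged regions and Jaccard indices were checked against bedtools. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.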

Results

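Accessible chromatin was mapped by ATAC-seq along the development of innate lymphoid cells (ILCs), lymphocytes without rearranged antigen receptors that include natural killer (NK) cells, ILC2 and ILC3. The 10 peak lists cover 6 populations sorted from mouse bone marrow and 4 mature populations. The bone marrow populations were haematopoietic stem cells (HSC), multipotent progenitors (MPP), common lymphoid progenitors (CLP), NK cell precursors (NKp), immature NK cells (iNK) and ILC2 precursors (ILC2p). The mature populations were splenic NK cells and, from the lamina propria of the small intestine, ILC2 and a pair of ILC3 populations. NCR ILC3 were sorted as NKp46-positive, NK1.1-negative cells and CD4 ILC3 as NKp46-negative, CD4-positive cells. Each list holds the peaks common to 2 replicates, and the depth behind it is unknown. All shares of regions below therefore lack a replicate error, and their 95% exact binomial intervals cover counting error only.

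The lists held between 34723 peaks in iNK and 55469 in NCR ILC3. HSC had 44308 peaks, MPP 40064, CLP 35811, NKp 44323, ILC2p 51134, NK 41209, ILC2 51135 and CD4 ILC3 42079. Mature lists averaged 47473 ± 6968 peaks (SD, n = 4) and bone marrow lists 41727 ± 6144 (SD, n = 6), a difference within the spread between populations (two-sided exact permutation p = 0.214). The mature lists covered more of the genome, 27.0 ± 5.17 Mb against 17.9 ± 3.30 Mb (SD, n = 4 and 6; exact permutation p = 0.0143), and their peaks were wider. Median peak width was 454 ± 22.6 bp in mature and 362 ± 19.0 bp in bone marrow lists (SD, n = 4 and 6; exact permutation p = 0.00476, the smallest that 210 splits can give). The comparison of widths was not among those fixed beforehand. Mature class, tissue of origin and sequencing run cannot be told apart in these comparisons, because every mature list and no bone marrow list has a library of run set D.

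A common core of accessible regions was kept from stem cells to all mature ILCs. Of 111690 merged regions, 11916 (10.7%) were listed in all 10 populations, with a median merged width of 1074 bp. A further 36622 (32.8%) were listed in a single population, with a median of 303 bp. A merged region spans all peaks that overlap in it, so its width tends to grow with the number of lists. Within single lists, the median length covered in regions of all 10 lists ran from 506 bp in CLP to 944 bp in NCR ILC3. The median peak widths of those lists were 356 and 481 bp. HSC had 4988 regions found in no other list (11.8% of its regions), ILC2 5464 (11.2%), NCR ILC3 5676 (10.5%) and ILC2p 4501 (9.25%). The iNK list had only 524 such regions (1.64%).

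Whether developmental class orders the accessible landscape was asked with the Jaccard index of covered base pairs. HSC and MPP had an index of 0.484 and MPP and CLP 0.465, but all libraries of these populations came from run set A, so development and run cannot be told apart there. iNK lay nearest to mature NK cells, at 0.577, and ILC2p nearest to ILC2, at 0.523, although ILC2p and ILC2 come from different tissues and share no run set. NKp lay nearest to iNK, at 0.479, and next to NK, at 0.448, but nearest to NK with peaks covering 50% of a region or with peak pairs overlapping by 1 bp. The 2 ILC3 lists were nearest to each other, at 0.524; with lists thinned at random to equal length, which removes most from the longest list and nothing from iNK, CD4 ILC3 was about as near to iNK (0.335) as to NCR ILC3 (0.336). The pairs of iNK with NK, NKp with iNK, NKp with NK and the 2 ILC3 lists each share a run set. The lowest similarity, 0.231, was between CLP and NCR ILC3. On average, pairs of lists within a class had an index of 0.404 and pairs between classes 0.350, a difference of 0.0540 (one-sided exact permutation p = 0.0429, 4 against 6 lists). This call was not firm: p rose to 0.0524 when regions in place of base pairs were compared, and it rose to between 0.0556 and 0.0952 without HSC, MPP, NKp, NCR ILC3 or CD4 ILC3. Similarity also differed by run set: the 24 pairs of lists that share a run set had a mean index of 0.421 and the 21 pairs that share none 0.324. Within the former the class difference was only 0.00765, and within the latter 0.0450. Most pairs that share none set HSC, MPP or CLP beside a later population, so run set and stage cannot be told apart here. The exceptions were ILC2 with ILC2p (0.523), NKp (0.381) and iNK (0.364).

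**Figure D1:**
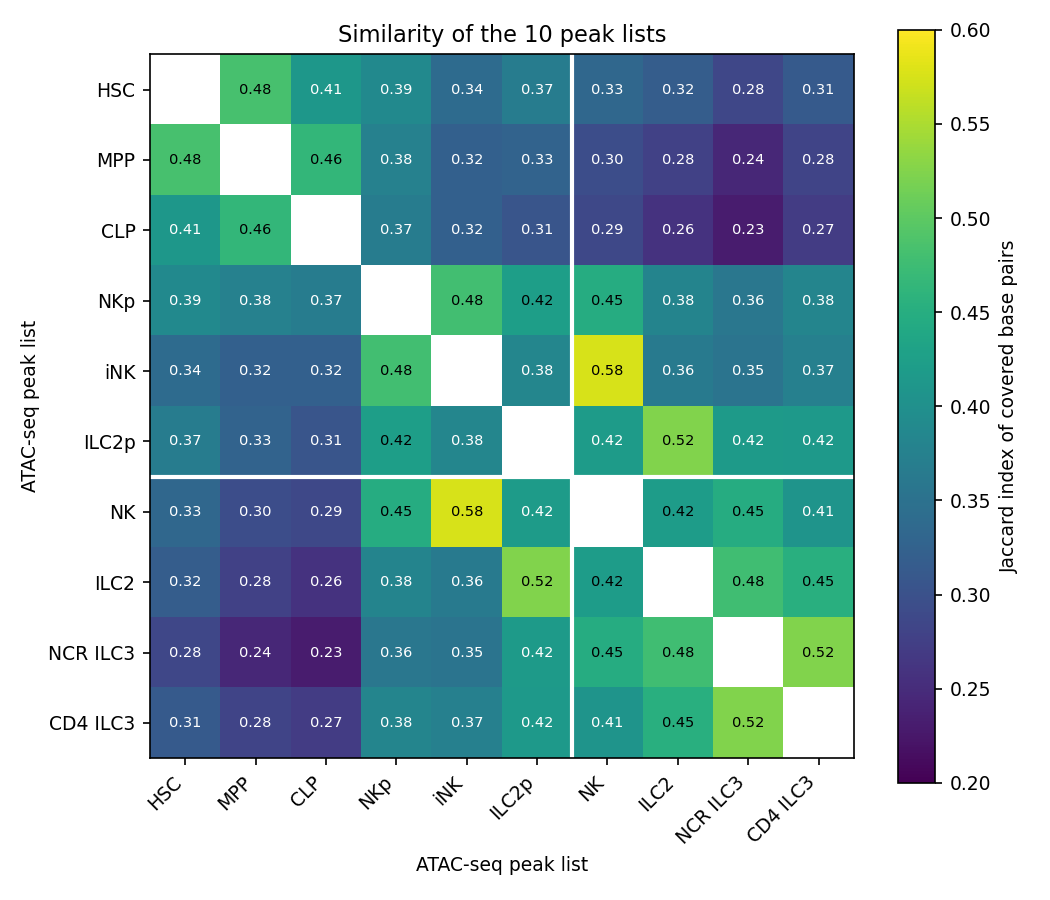
Jaccard index of covered base pairs for each pair of the 10 peak lists, with white lines between the 6 bone marrow and the 4 mature lists. The brightest cells pair iNK with NK (0.577), NCR ILC3 with CD4 ILC3 (0.524) and ILC2p with ILC2 (0.523), and the darkest pairs CLP with NCR ILC3 (0.231).

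Of the iNK regions, 90.6% (90.2 to 90.9) were listed in mature NK cells, 81.0% in NCR ILC3, 78.9% in NKp and 60.8% in HSC. Of the ILC2p regions, 73.7% (73.3 to 74.1) were listed in ILC2, 69.0% in NCR ILC3 and 54.5% in NK. The length of the list searched enters such shares, which limits their ranking. NKp regions were listed in 70.6% of cases in NCR ILC3, the longest list, in 69.1% in ILC2p, 65.2% in ILC2, 64.7% in NK and 60.2% in iNK, the shortest, although by the Jaccard index NKp was nearer to iNK (0.479) and NK (0.448) than to ILC2p (0.424), ILC2 (0.381) or NCR ILC3 (0.359). Likewise, 62.4% of HSC regions were listed in ILC2p and 57.6% in CLP, with Jaccard indices of 0.368 and 0.411. From HSC to MPP, 67.6% of regions were kept and 9854 were gained, and from MPP to CLP 65.9% were kept and 9203 were gained. Among the steps between bone marrow lists, the largest gains followed the CLP stage: 19610 regions were listed in NKp and not in CLP, and 27204 in ILC2p and not in CLP, which is 46.8% and 55.9% of the regions of those precursors. The run set also changes at this step, from A to B, and the CLP list, with 35811 peaks, was shorter than all but that of iNK, so these gains cannot be assigned to development alone. Regions lost at a step were narrower than those kept, for example 298 against 414 bp from CLP to NKp. iNK to NK was the step with the smallest loss, 9.45% of iNK regions. These are values without a test, since each population has a single list.

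When the regions of each mature population first became listed was traced along its path, in view of the series' stated theme, the developmental acquisition of regulatory regions. About as many mature regions as not were already listed in HSC: 55.1% for NK (54.6 to 55.6), 49.5% for ILC2 (49.1 to 50.0), 46.0% for NCR ILC3 (45.5 to 46.4) and 53.5% for CD4 ILC3 (53.0 to 53.9). MPP and CLP together added little, so that by the CLP stage 63.6% of NK, 57.2% of ILC2, 54.0% of NCR ILC3 and 61.0% of CD4 ILC3 regions had been listed. The lineage precursors then added a large block. For NK cells, 14.1% of regions were first listed in NKp and 10.1% in iNK. For ILC2, 21.2% were first listed in ILC2p. The run set changes from A to B between CLP and NKp or ILC2p, and both of these lists are longer than that of CLP. NK also has a library of set B, whereas ILC2 has none. These blocks therefore cannot be assigned to development alone. The remainder, listed at no earlier stage, was 12.3% for NK (11.9 to 12.6) and 21.5% for ILC2 (21.2 to 21.9). It was 46.0% for NCR ILC3 and 39.0% for CD4 ILC3, but no ILC3 precursor was among the lists, so these shares cannot be set against the other lineages. NK had NKp and iNK as precursor lists and ILC2 only ILC2p, so the NK and ILC2 remainders are not directly comparable either. The remainder depended on how an earlier presence was counted: with presence in at least 2 earlier lists required, it rose to 27.8% for NK and 45.2% for ILC2, and with peaks covering at least 50% of a region it was 21.5% for NK.

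**Figure D2:**
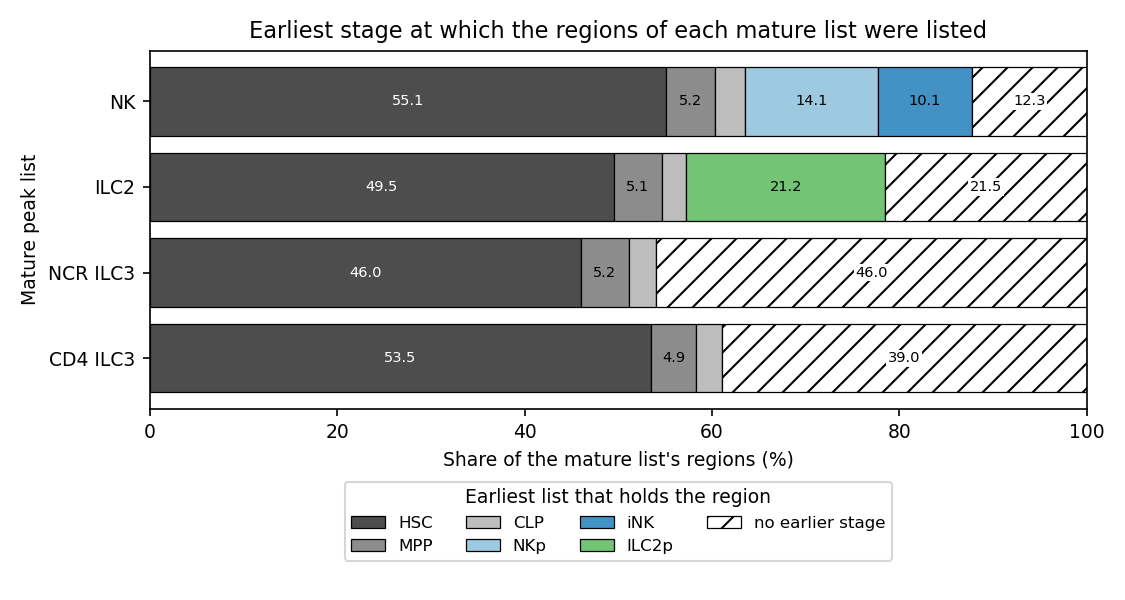
Share of the regions of each mature list (%, horizontal axis) by the earliest list along its developmental path that holds the region. HSC accounts for 46.0 to 55.1% in every bar, the precursors NKp, iNK and ILC2p add blocks of 14.1, 10.1 and 21.2%, and the hatched part, listed at no earlier stage, runs from 12.3% in NK to 46.0% in NCR ILC3. The paths differ in their precursor lists, so the hatched parts are not directly comparable. The run set changes from A to B between CLP and NKp or ILC2p, so the precursor blocks cannot be assigned to development alone.

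Stem cell regions dropped out of the lists of all 4 mature populations to a like extent. Of 42298 HSC regions, 50.8% were listed in NK, 56.9% in ILC2, 58.8% in NCR ILC3 and 50.8% in CD4 ILC3, and 16805 (39.7%) were listed in all 4 mature populations. A total of 13679 HSC regions, 32.3% (31.9 to 32.8), were listed in no mature population. Of these, 57.7% (56.8 to 58.5) were still listed in MPP or CLP. All libraries of HSC, MPP and CLP came from run set A and no mature library did. Loss along development therefore cannot be told apart from run set here. ILC2p kept 62.4% of the HSC regions and iNK 46.0%, the highest and lowest shares among the bone marrow lists that follow CLP. The ILC2p list was also the longest of the bone marrow lists and the iNK list the shortest. Among the mature lists, the higher shares likewise belonged to the longer lists, ILC2 and NCR ILC3.

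Regions specific to NK cells and to ILC2 were present in the bone marrow most often in precursors of the same lineage. NK, ILC2, NCR ILC3 and CD4 ILC3 had 7181, 10750, 8406 and 3940 regions listed in no other mature population. Of the ILC2-only regions, 42.1% (41.2 to 43.0) were listed in ILC2p, against 13.9% of NK-only, 17.4% of NCR ILC3-only and 11.3% of CD4 ILC3-only regions. Of the NK-only regions, 51.2% (50.1 to 52.4) were listed in iNK and 28.3% (27.2 to 29.3) in NKp, against 1.55% and 10.4% of ILC2-only regions. In HSC, by contrast, all 4 sets had similar shares, from 11.6 to 13.1%. Any bone marrow list held 66.1% of NK-only and 49.2% of ILC2-only regions, but 32.5% of NCR ILC3-only (31.5 to 33.5) and 28.3% of CD4 ILC3-only regions (26.9 to 29.8). No ILC3 precursor was among the lists. The CD4 ILC3-only regions had no list that stood out, with 13.0% in HSC and 12.8% in NKp. The 21110 regions listed in all 4 mature populations were present in 94.0% of cases in ILC2p, 90.5% in NKp and 79.6% in HSC. With lists thinned to equal length, the share of ILC2-only regions in iNK rose to 5.80%.

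**Figure D3:**
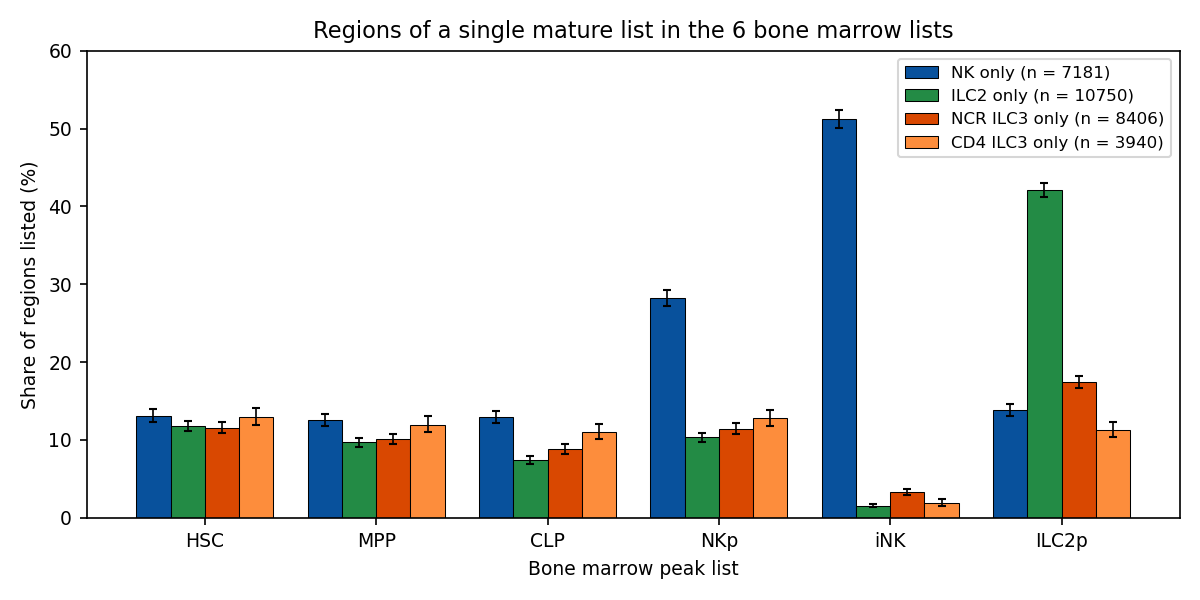
Share (%, vertical axis) of the regions listed in a single mature population that were also listed in each of the 6 bone marrow populations, with 95% exact binomial intervals as error bars. NK-only regions stand out in NKp (28.3%) and iNK (51.2%) and ILC2-only regions in ILC2p (42.1%), while in HSC the 4 sets lie between 11.6 and 13.1%.

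The selectivity of the precursors was expressed as a ratio of shares. ILC2p held ILC2-only regions 3.04 times as often as NK-only regions (2.86 to 3.23). NKp held NK-only regions 2.73 times as often as ILC2-only regions (2.55 to 2.92), and iNK 33.0 times as often (28.3 to 38.4). CLP already held NK-only regions 1.74 times as often (1.59 to 1.90), and HSC held ILC2-only regions nearly as often as NK-only ones, with a ratio of 0.901 (0.832 to 0.974). NKp and ILC2p came from the same run set, B, so their opposite preferences were seen within that set. NK also has a library of set B, as has iNK, while ILC2 has none. The NKp and iNK ratios thus run along a shared run set, and the ILC2p ratio runs against it. In lists thinned to equal length the ILC2p ratio was 1.89, the NKp ratio 2.24 and the iNK ratio 9.41. The iNK ratio also fell to 18.4 with 200 bp around each peak centre and to 10.8 with 50% reciprocal overlap. Among the 12217 NKp regions listed in none of HSC, MPP and CLP, 45.0% were listed in NK and 38.4% in ILC2; among the 17722 such regions of ILC2p, 58.2% were listed in ILC2 and 25.8% in NK.

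The ILC3 populations shared most of their regions, and the NCR ILC3 list was the longer. Of the CD4 ILC3 regions, 85.9% (85.5 to 86.2) were listed in NCR ILC3, while 63.8% (63.4 to 64.2) of NCR ILC3 regions were listed in CD4 ILC3. The 19606 regions listed in NCR ILC3 and not in CD4 ILC3 were often those of other mature ILCs, with 36.0% listed in NK (35.4 to 36.7) and 41.4% in ILC2 (40.7 to 42.1). Among the 5673 regions listed in CD4 ILC3 and not in NCR ILC3, these shares were 11.2% (10.4 to 12.0) and 24.5% (23.4 to 25.6). Over all regions of each list the order was the other way. In NK, 55.5% of NCR ILC3 and 58.7% of CD4 ILC3 regions were listed, and in ILC2 65.2% and 71.1%. Regions listed in NK and NCR ILC3 and in neither other mature population numbered 3091, against 345 for NK and CD4 ILC3. The NCR ILC3 list had 55469 peaks and the CD4 ILC3 list 42079, and both shares of a pair have the same regions as numerator, so the asymmetry of 85.9% and 63.8% follows from list length. The ratio of 3091 to 345, 8.96, fell to 4.96 with 200 bp around each peak centre, 3.51 with the NCR ILC3 list reduced to its widest peaks, as many as CD4 ILC3 has, 3.38 with 50% reciprocal overlap and 1.28 with lists thinned at random. The ratio of the shares in NK between the 2 sets, 3.22, turned to 0.886 in the thinned lists and was 1.55 with 200 bp around each peak centre and 1.32 with 50% reciprocal overlap.

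The densest windows of NK-only and ILC2-only regions held more regions than any random draw. The densest 100 kb window of NK-only regions, on chromosome 9 from 118300001 to 118400000, held 14 of them among 18 regions in all; 7 were listed in NKp, 7 in iNK, 2 in MPP and 1 in ILC2p, and none in HSC or CLP. The highest of 1000 random draws was 9. The next NK windows, with 11, 10, 9 and 9 regions, started at 165000001 on chromosome 2, 114000001 on chromosome 5, 103400001 on chromosome 2 and 83300001 on chromosome 11. For ILC2, a window on chromosome 2 from 9200001 to 9300000 and another on chromosome 3 from 29800001 to 29900000 each held 12 ILC2-only regions, 5 of them listed in ILC2p and none in HSC, MPP, CLP or iNK, where the highest random draw was 11. A further ILC2 window lay nearby on chromosome 2, from 9000001 to 9100000, with 11 regions, and the remaining windows, also with 11, were on chromosome 1 at 21200001 and 168700001. All 12 regions in the chromosome 3 window were ILC2-only, and 1 of them was listed in NKp.

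For the ILC3 populations the densest windows held fewer regions, but the sets differ in size and strength of clustering was not compared. The densest NCR ILC3-only windows held 7 regions, a density that 47.8% of the random draws reached. They were on chromosome 8 from 9400001, chromosome 12 from 81100001 and from 115300001 and chromosome 13 from 56200001, and the fifth window, on chromosome 2 from 154600001, held 6. With peaks covering 50% of a region the densest NCR ILC3-only window held 10. The densest CD4 ILC3-only window, on chromosome 10 from 10600001 to 10700000, held 7 of its 8 regions, and 1% of random draws reached this density. None of the 7 was listed in any bone marrow population. The other 4 CD4 ILC3 windows held 6 regions each, where the fifth window of the random draws held at most 5. They were on chromosome 5 from 129000001, chromosome 13 from 3700001, chromosome 17 from 8400001 and chromosome 19 from 22600001. No gene annotation of the build was used, so the windows are given by position. The NK maximum of 14 fell to 8 with the wider peaks of each list alone.

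**Figure D4:**
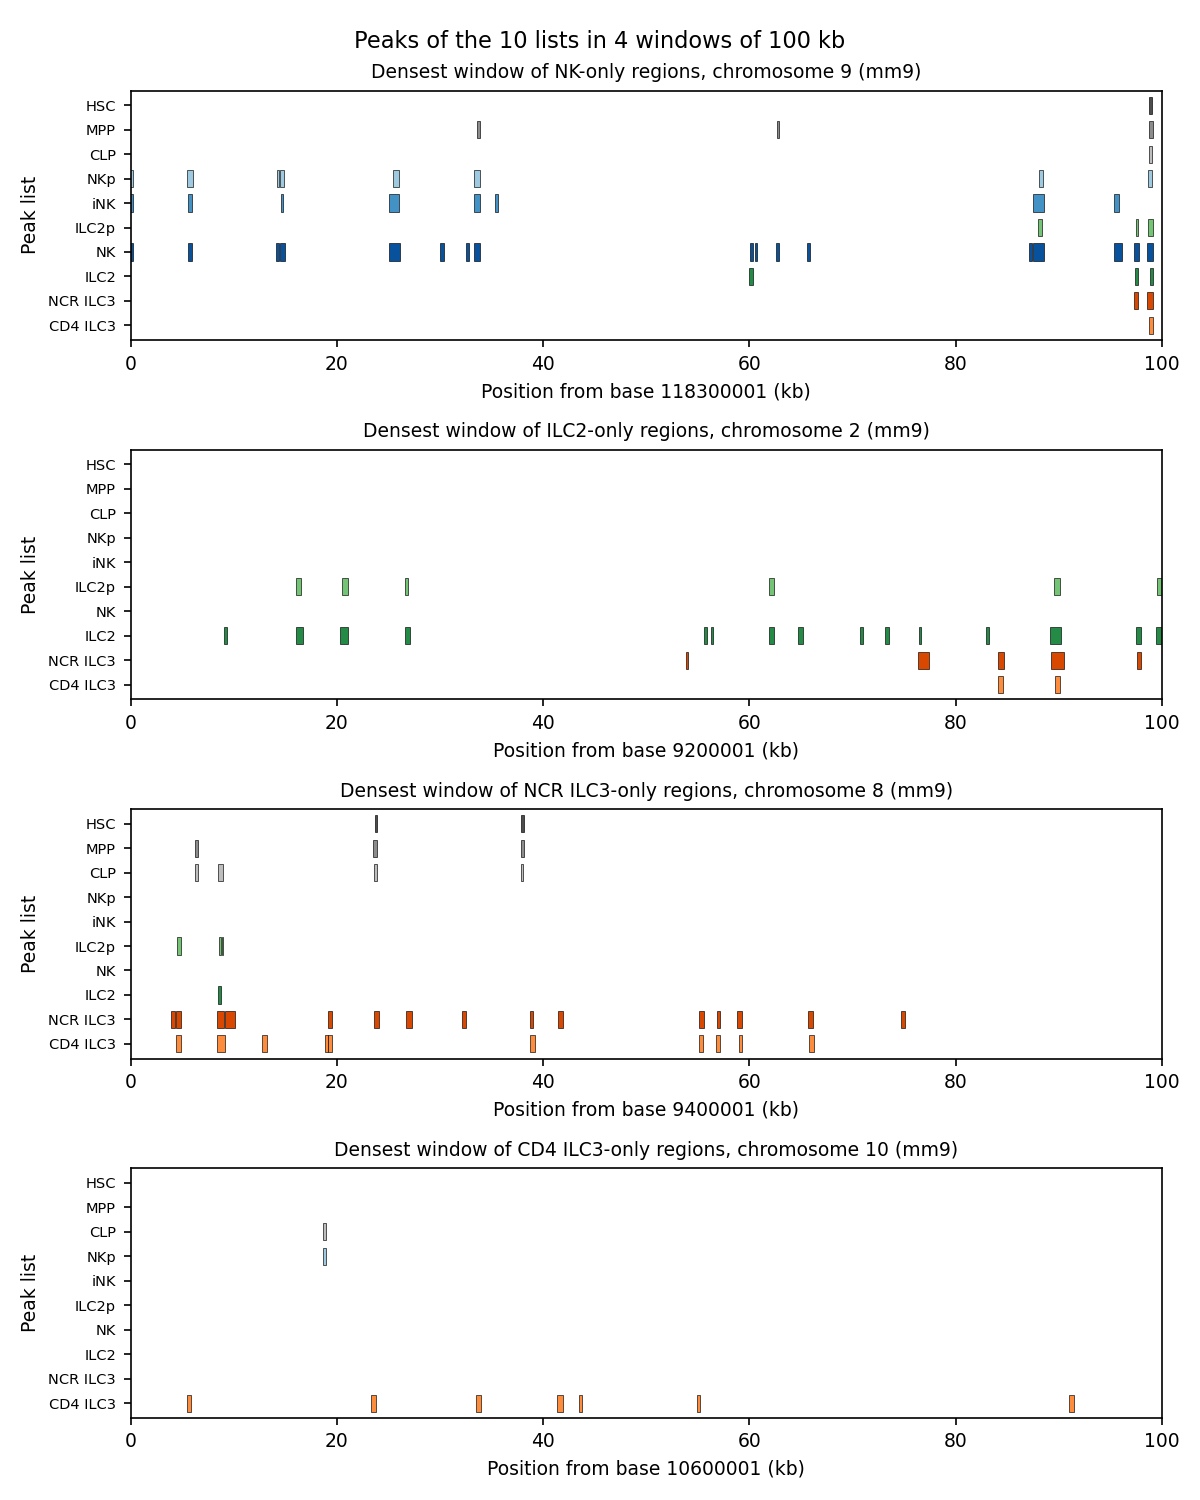
Peaks of the 10 lists (rows) along the densest 100 kb window of regions specific to each mature population, with position in kb from the window start in mm9. The NK window shows 14 NK-only regions of which 7 recur in iNK, the ILC2 window 12 ILC2-only regions of which 5 recur in ILC2p, and the CD4 ILC3 window 7 regions seen in no other mature list.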

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

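Leaving out each list in turn, keeping only the wider peaks of each list and reducing the NCR ILC3 or HSC list to its widest peaks were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each list holds only the peaks common to its 2 replicates, and for the same reason no replicate could be left out. A stricter threshold by score could not be applied, since the score is constant, and the gene list and promoter comparisons with their alternatives were not run for want of an annotation of the build. Of 68 values under alternatives to the main comparisons, 27 stayed within their interval or on the same side of the threshold. A further 32 left their interval, 8 lost a call and 1 gained a call. A change of direction could be scored only for ratios and for the tests across lists, and none was seen among the main comparisons. Among further values in the text, 80 stayed, 89 left their interval and 1 ratio changed direction. Window counts have no interval and were scored as staying when within a fixed factor of the reported count. On autosomes alone no value of the main comparisons left its interval or changed its call. Depth is unknown, and intervals over so many regions are narrow, so shifts of a few percentage points leave them.

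The peak number difference became a call in covered length (9.08 Mb, exact permutation p = 0.0143). The similarity difference of 0.0540 lost its call with peaks covering 50% of a region (0.0437, exact permutation p = 0.0571), by regions (0.0383, p = 0.0524), with regions in at most 9 lists (0.0359, p = 0.0905), and without HSC (0.0483), MPP (0.0420), NKp (0.0615), NCR ILC3 (0.0292) or CD4 ILC3 (0.0411), with p from 0.0556 to 0.0952. The cause was not tested.

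The next values are, in order, the share of iNK regions in NK (90.6% as reported), of ILC2 regions at no earlier stage (21.5%), of HSC regions in no mature list (32.3%), of ILC2-only regions in ILC2p (42.1%), the ILC2p ratio (3.04) and the share of CD4 ILC3 regions in NCR ILC3 (85.9%). They were 87.1%, 30.0%, 42.2%, 39.8%, 3.23 and 82.3% with peaks covering 50% of a region; 86.0%, 24.0%, 33.8%, 39.2%, 2.69 and 80.1% with 200 bp around the centre; and 76.9%, 28.8%, 35.2%, 31.7%, 1.89 and 54.3% with thinned lists, in which shared regions drop out of either list by construction. With 50% reciprocal overlap they were 77.1%, 27.6%, 38.4%, 37.3%, 2.47 and 73.6%. The wider peaks gave 85.8%, 23.2%, 39.0%, 2.72 and 83.9%, the HSC share staying within its interval. Peak pairs overlapping by 1 bp moved only the HSC share (31.2%) and the ILC3 share (86.3%). Requiring 2 earlier lists gave 45.2% for ILC2. The ratio of NK shares between regions of a single ILC3 list, 3.22, turned to 0.886 with thinned lists, and was 1.55 with 200 bp around the centre and 1.32 with 50% reciprocal overlap. By the Jaccard index of regions in thinned lists, CD4 ILC3 was nearer to iNK (0.374) than to NCR ILC3 (0.368). In each setting that merged or paired peaks differently, or used other peaks, the ILC2-only regions had the highest share in ILC2p and the NK-only regions exceeded them in NKp and iNK.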

Other observations

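Among the tests below, those that compare peak width between mature and bone marrow lists were chosen only after the result was seen; the values of the other tests had not been seen when they were set out. The combinations of the reduced NCR ILC3 list with other alternatives were added after its own value was seen, and the reduced HSC list was chosen after the values with lists thinned at random were seen.

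The intestinal populations shared a set of regions that were absent from the list of splenic NK cells. ILC2, NCR ILC3 and CD4 ILC3 together listed 6041 regions absent from NK, compared with 3972 absent only from CD4 ILC3 among the mature populations, 1834 absent only from ILC2 and 290 absent only from NCR ILC3. Of this set 79.7% (78.6 to 80.7) was also listed in some bone marrow population, less than the 94.3%, 90.2% and 96.6% of the other 3 sets in that order. ILC2p held 70.3% (69.1 to 71.4), NKp 39.7% (38.5 to 41.0), HSC 35.9% (34.7 to 37.2) and iNK 13.1% (12.3 to 14.0). The other 3 sets contain NK regions by definition, and iNK held 62.9%, 71.8% and 61.7% of them in the same order. NKp and iNK are NK precursors and no ILC3 precursor was listed. The lower share in bone marrow therefore cannot be told apart from the choice of bone marrow lists. Tissue and lineage cannot be separated here, since NK cells were the only mature population taken from spleen. The counts of regions absent from a single mature list also run in reverse order of list length. NK had 38995 regions, CD4 ILC3 40166, ILC2 48570 and NCR ILC3 54099. The larger number absent from NK alone thus cannot be told apart from the shorter NK list.

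Precursors also listed regions found neither in HSC, MPP and CLP nor in mature cells, most of them in a single precursor. Of the regions absent from HSC, MPP and CLP, 31.9% (31.0 to 32.7) in NKp, 27.9% (27.3 to 28.6) in ILC2p and 8.02% (7.49 to 8.58) in iNK were listed in no mature population; for iNK these were 790 regions, 524 of them in iNK alone. Of all 12217 NKp regions absent from HSC, MPP and CLP, whether or not listed in a mature population, 38.2% were also listed in ILC2p. NK listed 45.0% of them and NCR ILC3 49.5%, whose list is longer, with 54099 regions against 38995 in NK. Dixon's rule for outliers, applied to the 4 mature or the 6 bone marrow lists, flagged no list in 14 sets of values. With so few lists the rule finds only extreme values. It did not flag iNK, with 1.64% of its regions in no other list against 7.83 to 11.8% in the other bone marrow lists.

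Mature lists had wider peaks than bone marrow lists, by a ratio of 1.25 in median width. A mix of regions richer in wide, shared sites is argued against by the 11916 regions common to all populations, where the same regions covered 810 bp in mature and 581 bp in bone marrow lists, a ratio of 1.39 (exact permutation p = 0.00476, n = 4 and 6). A difference acting on whole lists, such as depth or sequencing run, may account for it, since every mature list and no bone marrow list has a library of run set D. Broader opening in mature cells was not tested and stays open as well.

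From stem cells to CLP, regions of ILC2 thinned out more than those of NK, against a general fall. The CLP to HSC ratio of listed regions was 0.816 over all regions, 0.628 for ILC2-only (11.8% in HSC, 7.42% in CLP), 0.762 for NCR ILC3-only, 0.853 for CD4 ILC3-only, 0.870 for regions of all 4 mature lists and 0.984 for NK-only regions; the quotient of the ILC2-only and NK-only ratios was 0.639 (0.563 to 0.725). The shorter CLP list is argued against as the whole cause of that quotient, which was 0.674 (0.589 to 0.772) with the HSC list reduced to its widest peaks, as many as CLP has. Thinning all lists at random gave 0.708, but it also changes which regions count as ILC2-only or NK-only and decides nothing. Narrower ILC2-only peaks in the mature list are argued against as well, since the quotient was 0.648 (0.570 to 0.735) after matching on mature peak width. The median widths, 350 bp for ILC2-only and 364 bp for NK-only peaks, were close before matching. Peak width in HSC and CLP was not matched, so narrower ILC2-only peaks in those lists stay open. As a hypothesis, the lymphoid progenitor may keep NK regions more than ILC2 regions; other depth differences between the lists stay open.

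The NCR ILC3 list held more NK regions than the CD4 ILC3 list, 30007 against 23579, but it was also the longer. As a share of each list the order was reversed, with 55.5% of NCR ILC3 and 58.7% of CD4 ILC3 regions listed in NK. The ratios of NK shares below concern only regions listed in a single ILC3 list. The NCR ILC3 sort selected NK1.1-negative cells. An admixture of NK cells large enough to bring in most of the widest NK regions is argued against. Of the NK regions absent from ILC2 and CD4 ILC3, only 40.5% (37.4 to 43.5) of the widest 10% were in the NCR ILC3 list. The share was 35.1% in the next 10% and between 25.7 and 31.2% in the others, with 29.2% in the narrowest 10%. A smaller admixture need not bring in most of the widest regions, so the test cannot exclude it. Whether the longer NCR ILC3 list is the whole cause was not settled. Reduced to its widest peaks, as many as CD4 ILC3 has, it gave a ratio of NK shares of 1.59 (1.53 to 1.65), above the bound of 1.5 set beforehand. The ratio was below that bound with 200 bp around each centre, 1.28 (1.24 to 1.32), or 50% reciprocal overlap, 1.27 (1.23 to 1.31), in addition. Only the NCR ILC3 list was cut by width, so the sets compared also differ in which narrow peaks they keep. List length and peak width may still account for much of the 3.22 seen with the full lists, and random thinning, at 0.886, does not decide, since it removes more shared regions from the longer list and so moves them into the CD4 ILC3 set. Shared use of regions by NKp46-positive populations was not tested and stays open.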
